A study of Mus musculus with 5 samples.

How the data were processed

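The 5 libraries came from thymocytes of Rag2-/- mice: E2A at day 0 and day 2, H3K4me1 at day 0 and day 2, and an input of untreated cells, with 1 library per group. Groups were taken from the titles in the labels. Per the labels' protocols, chromatin was sonicated and immunoprecipitated, and libraries were amplified by 18 cycles of PCR, size selected on a gel and sequenced on the Genome Analyzer II. Per the submitters' processing notes, CASAVA, Bowtie and HOMER were used and the genome build was mm8; their versions and the role of each tool are not given in the sources used here.

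The deposited files list 30 bp alignments with, per position and strand, the count of reads mapped there, which are raw counts without normalization. Each position and strand appears 1 time, so repeated reads had already been gathered in the deposited files, as their values show. Here each position and strand was used as 1 tag, and chromosomes 1 to 19, X and Y were kept. PCR copies cannot be told from independent fragments that start at the same base, and using 1 tag caps very dense sites. Library totals and reads were 8281250 tags and 8462549 reads for E2A at day 0, 7293482 and 7454885 for E2A at day 2, 16536824 and 16862898 for H3K4me1 at day 0, 12715085 and 12940277 for H3K4me1 at day 2, and 9051099 and 9281710 for the input.

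Fragment length was estimated from the distance between the strands, searched from 60 bp upward. It was 85 and 87 bp in the H3K4me1 libraries and 79 bp in the input, while both E2A libraries had their maximum at the lower limit of the search, because a peak at the read length dominated. The mean of the H3K4me1 values, 86 bp, was therefore used for every library, and tags were moved by this distance divided between the strands. This is a departure from the design, which foresaw an estimate per library, and it was made after the data were seen.

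E2A peaks were called with a procedure written after that of HOMER, without HOMER itself. It used 200 bp windows at least 400 bp apart, a Poisson false discovery rate of 0.001 against the genome mean with a mappable genome of 2000000000 bp, at least 4 fold over input and at least 4 fold over the surrounding 10000 bp. The genome mean as a lower limit for the input density, a Poisson p of at most 0.0001 against the scaled input, and the genome size were fixed after the design was written. First calls with another fragment length had been looked at before the final settings. H3K4me1 regions were 1000 bp bins at least 3 fold over input with a Benjamini-Hochberg adjusted Poisson false discovery rate of 0.001, joined over gaps of up to 1000 bp. The untreated input served as control on both days.

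Peaks of the days were shared when their centres lay within 200 bp. Ratios of day 2 to day 0 are of tags scaled to a common library total (RPM), with exact conditional binomial 95% intervals, and a peak or region was higher or lower when the ratio was at least 2 either way and the interval left out 1. Medians over peaks have distribution-free binomial intervals, shares have exact Clopper-Pearson intervals, and where 1 side had 0 tags a floor of 3 counts gave a bound. These intervals and floors cover counting error only, and no p-value is given across peaks or regions, since 1 library per group leaves nothing to test the conditions with. Peaks were called narrow when the interquartile range of the tag 5' ends of both E2A libraries within 250 bp was below 60 bp, a boundary set after the data were seen.

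Random positions were drawn on the same chromosomes, 1 per peak. Counting error between libraries was measured by dividing the pooled autosomal tags of the days at random into libraries of the real sizes, 10 times for each antibody, and calling peaks or regions anew. The comparisons by chromosome used 10 kb bins without a peak or region. The random divisions, the chromosome comparison, the trough in H3K4me1, the H3K4me1 ratios without the peak centre, the neighbouring peaks and the count minimum of 20 tags were chosen after the data were seen.

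Named regions followed a rule fixed before the data were examined: for each comparison the 5 regions with the highest RPM on each day, the 5 with the highest and the 5 with the lowest ratio, ranked by the bound of the interval nearest to 1, leaving out regions whose input density was over 5 times the genome mean. This left out 39 E2A peaks and 3 H3K4me1 regions. The same rule was applied to the spread peaks alone, which added the chr4 site at 41064631 and the chr11 site at 117768341. Regions are given by mm8 coordinates, counted from 1. The reference table of genes used the GRCm38 assembly, so its positions were not set against the mm8 alignments, gene lists fixed in advance were not analysed here, and Rag2, the gene these mice lack, was not placed.

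The procedures were tested on simulated libraries. For E2A, planted sites of 20 or 40 expected tags at day 0 were all found, and those of 10 tags in 69.9%, 56.7% and 84.5% of cases for a true ratio of 0.25, 0.5 and 1. At 20 tags, 76.1% of found sites with a true ratio of 0.25 and 35.1% of those with 0.5 were called lower, against 0.966% of those with 1, and 23 of 943 called peaks were not planted. For H3K4me1, all 200 planted regions with a true ratio of 0.333 were found and 98.5% of them were called lower, with a median measured ratio of 0.411, 0 of 400 unchanged regions were called, and 64 of 664 called regions were not planted. The planted H3K4me1 regions were 5 kb long, with 330 expected tags at day 0. The real regions had a median length of 1 kb, and autosomal regions of 1 kb had a median of 31 tags at day 0. The simulation therefore does not show how well such short regions are called. For E2A, the simulated background was even within each 10 kb bin, so it held no pile-ups like the narrow peaks. Planted sites were not matched to the spread of tags in real peaks. The shares found and not planted therefore do not carry over to the real E2A peaks.

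Alternatives fixed before the data were examined covered keeping all reads, a higher fold over input, equal depth, another fragment length, other windows and distances, other scalings, subtraction of the input and another rule for sharing. Autosomes alone and spread peaks alone were added after the data were seen. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.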

Results

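E2A and the enhancer-associated histone mark H3K4me1 were mapped by chromatin immunoprecipitation and sequencing in thymocytes of Rag2-/- mice on the C57BL/6 background. E2A is a basic helix-loop-helix transcription factor that acts at early steps of T cell development. Thymocytes without Rag2 cannot rearrange their antigen receptor genes and stop at the DN3 stage. Injection of an antibody to CD3e, a signalling chain of the T cell receptor complex, stands in for the missing receptor signal and moves the cells on to DN4. Cells of untreated mice (day 0) and of mice injected 2 days earlier (day 2) each gave 1 E2A library and 1 H3K4me1 library, and untreated cells gave 1 input library. Each group thus held 1 library, so every interval below covers counting error only, and every difference is between libraries and has no replicate check.

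The E2A libraries held 8281250 tags at day 0 and 7293482 at day 2, where a tag is 1 mapped position and strand. The H3K4me1 libraries held 16536824 and 12715085 tags, and the input held 9051099. Between 98.2% and 98.8% of the tags of a library had been read 1 time. The H3K4me1 libraries therefore allowed finer comparisons than the E2A libraries, in which a 200 bp window counted as a possible peak from 10 tags at day 0 and 9 tags at day 2. Densities are tags scaled to a common library total (RPM).

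E2A peaks numbered 904 in the day 0 library and 497 in the day 2 library, and 305 of them were found on both days. These counts depended on the settings. With all reads kept they were 1160 at day 0, 767 at day 2 and 501 shared. With a fragment length of 150 bp they were 790, 277 and 193. The highest peak on both days was chr17:4582863-4583062 (mm8), with 119 tags at day 0 and 112 at day 2. The next highest was chr6:125842645-125842844, with 72 and 71 tags. The other day 0 sites among the 5 highest were chr8:87614879-87615078 with 72 tags, chr13:64425808-64426007 with 61 tags and chr19:45613475-45613674 with 58 tags. At day 2 the other sites among the 5 highest were chr9:62406537-62406736 with 55 tags, chr11:25000073-25000272 with 49 tags and chr3:153061097-153061296 with 45 tags. Regions with an input density over 5 times the genome mean were left out of this and the later rankings. None of these 8 sites had more than 3 input tags, which that rule and the criteria for a peak set in part. Genes were not assigned, because no annotation on the mm8 build was used here.

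The E2A peaks fell into 2 kinds by the spread of their tags. In 354 of the 1096 peaks called on either day, the interquartile range of the tag 5' ends was below 60 bp, with a median of 35 bp and a median distance of 34 bp between the strands, close to the 30 bp read length. These narrow peaks numbered 249 at day 0 and 290 at day 2. The other 742 peaks, called spread peaks, had a median interquartile range of 119 bp and a median strand distance of 77 bp, and 655 of them were called at day 0 and 207 at day 2. The chr9, chr11 and chr3 sites among the 5 highest at day 2 were narrow. The 60 bp boundary was chosen after the data were seen, and the chr17 and chr6 sites, though spread by this measure, had strand distances of only 36 and 59 bp.

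**Figure D1:**
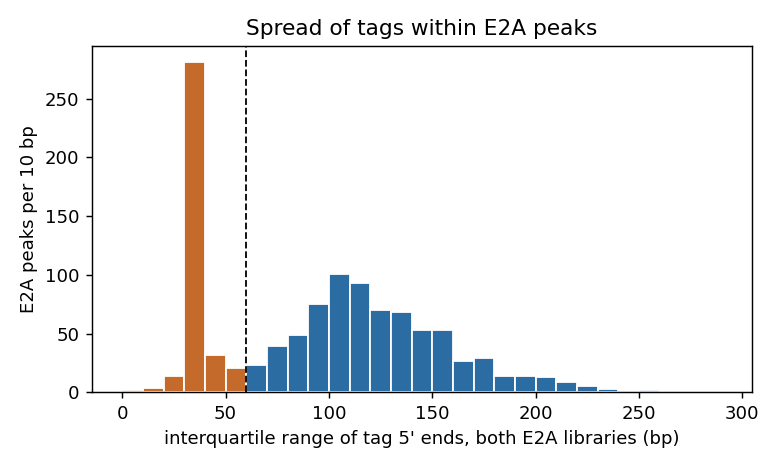
Number of E2A peaks (vertical axis, per 10 bp class) by the interquartile range of the tag 5' ends within 250 bp of the peak centre, both E2A libraries pooled (horizontal axis, bp). The dashed line at 60 bp parts the 354 narrow peaks (orange) from the 742 spread peaks (blue).

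The comparison of day 2 with day 0 asks how E2A occupancy differs after the CD3e signal. Over the 1096 peaks the median ratio of E2A density at day 2 to day 0 was 0.611 (95% interval of the median over peaks 0.568 to 0.662). By a ratio of at least 2 with an exact binomial interval that leaves out 1, 299 peaks were lower at day 2, 42 were higher and 755 met neither condition; with all reads kept 347 were lower and 92 higher. The lower density lay in the spread peaks, where the median ratio was 0.413 (0.378 to 0.444), with 290 of 742 lower and 32 higher. In the narrow peaks the median ratio was 1.14 (1.08 to 1.14), with 9 of 354 lower and 10 higher. Spread peaks held 0.139% of all E2A tags at day 0, 0.0682% at day 2 and 0.0145% of the input tags.

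Among the spread peaks, 120 were called on both days, 535 at day 0 only and 87 at day 2 only. Those called on both days had a median ratio of 0.739 (0.681 to 0.811), against 0.310 for day 0 only and 2.46 for day 2 only. The ratios use the same counts that called the peaks. The median of 0.413 over all spread peaks therefore depends in part on this selection, which its interval does not cover. Counting error was measured on the autosomes, where peaks were called anew and the real libraries gave a larger set, with 788 spread peaks at day 0 and 339 spread peaks lower at day 2. When the pooled autosomal E2A tags were divided at random into 2 libraries of the real sizes, 10 times, at most 39 spread peaks were lower at day 2. The same divisions gave 30 to 66 spread peaks higher at day 2, against 30 for the real libraries. Of the day 0 spread peaks, they placed only 50.2% to 57.8% on both days, against 15.7% for the real libraries. These divisions hold no drop between the days, so they do not show whether the peaks with more E2A at day 2 exceed counting error.

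The spread sites with the most E2A tags differed in how far their density was lower. At chr8:87614879-87615078 the count went from 72 to 20 tags, a ratio of 0.315 (0.182 to 0.524), and at chr19:45613475-45613674 from 58 to 19 tags, a ratio of 0.372 (0.209 to 0.634). The ratio was 0.726 (0.473 to 1.103) at chr13:64425808-64426007, 0.784 (0.505 to 1.21) at chr11:117768341-117768540 and 1.19 (0.755 to 1.89) at chr4:41064631-41064830, so these 3 sites did not differ beyond counting error. The same held for the chr17 and chr6 sites, with ratios of 1.07 (0.818 to 1.39) and 1.12 (0.795 to 1.58).

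The 5 sites with the lowest ratios were all spread peaks called at day 0 only. The count went from 44 to 3 tags at chr8:86954401-86954600, a ratio of 0.0774 (0.0154 to 0.241), and from 34 to 2 tags at chr2:180002427-180002626, a ratio of 0.0668 (0.00777 to 0.261). At chr13:54993935-54994134 and chr6:91623856-91624055 it went from 26 tags to 1, a ratio of 0.0437 (0.00107 to 0.266) in each case. At chr8:11506898-11507097 it went from 18 tags to 0, which is at least 5.28-fold lower when the 0 is set to a floor of 3 counts, and at least 3.87-fold by the exact interval, which also covers the error of the 18 tags. The 5 sites with the highest ratios, chr13:10999390-10999589, chr14:63166081-63166280, chr18:13261497-13261696, chr18:42515549-42515748 and chr2:136639061-136639260, each had 0 tags at day 0 and 9 at day 2, at least 3.41-fold higher with the same floor and at least 2.24-fold by the exact interval. Those 9 tags equal the threshold for a peak.

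**Figure D2:**
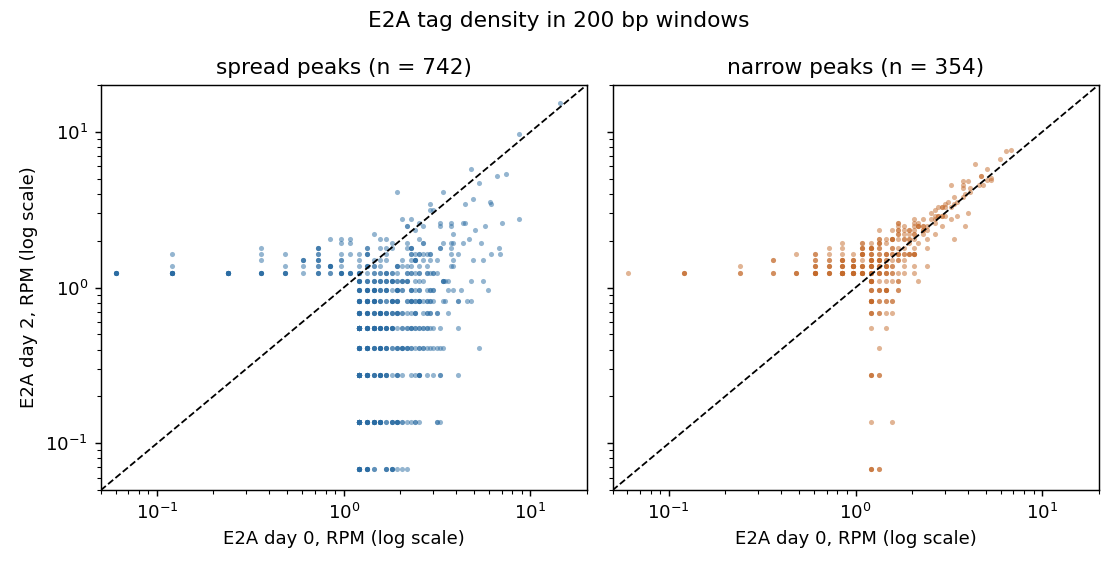
E2A density (RPM) in 200 bp windows at day 0 (horizontal, log scale) and day 2 (vertical, log scale), 1 point per peak, for 742 spread peaks (left) and 354 narrow peaks (right); windows with 0 tags are drawn at 0.5 tags and the dashed line marks equal values. Most spread peaks lie below the line, with a median ratio of 0.413, and the narrow peaks lie around it, with a median ratio of 1.14.

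H3K4me1 covered 39120 regions and 96.4 Mb at day 0, and 37947 regions and 91.5 Mb at day 2, against 18675 and 19614 regions at 5 fold over input. Of the base pairs covered at day 0, 70.5% lay in day 2 regions, and of those covered at day 2, 74.2% lay in day 0 regions. Over the 45850 regions of either day the median ratio of H3K4me1 density at day 2 to day 0 was 1.005 (1.0004 to 1.012). By the same criterion as for E2A, 3916 regions were higher at day 2, 3117 were lower and 38817 (84.7%) met neither condition; with the input subtracted 5325 were higher and 4811 lower. Random divisions of the pooled autosomal tags gave 436 to 494 higher and 352 to 408 lower regions, against 4083 and 3002 for the real libraries, so the regions of both directions exceeded counting error between 2 libraries of one pool. These divisions shared only 83.6% to 84.0% of day 0 base pairs and 82.6% to 83.1% of day 2 base pairs. The real autosomal libraries shared 72.3% and 73.0%. Counting error alone thus left part of the base pairs unshared.

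The median region was 1 kb long at either day and the longest region of a single day spanned 59 kb; the regions named here join both days. Among the 6235 autosomal regions of 5 kb or more, 149 were higher and 105 lower by this criterion. The region with the most H3K4me1 tags on both days was chr1:43393001-43452000, with 4001 tags at day 0 and 3605 at day 2, a ratio of 1.17 (1.12 to 1.23). At chr8:127131001-127183000 the ratio was 0.875 (0.833 to 0.919) and at chr1:36823001-36883000 it was 0.925 (0.878 to 0.975). The ratio was 1.21 (1.15 to 1.26) at chr9:32236001-32289000 and 1.17 (1.11 to 1.23) at chr12:74506001-74558000. Among the 5 highest at day 2 were also chr12:107517001-107564000, with a ratio of 1.34 (1.28 to 1.42), and chr11:11592001-11643000, with a ratio of 1.28 (1.22 to 1.35).

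The largest differences in H3K4me1 lay in short regions. The count went from 7 to 81 tags at chr14:9045001-9047000, a ratio of 15.0 (6.98 to 38.6), and from 8 to 83 at chr1:60657001-60659000, a ratio of 13.5 (6.54 to 32.3). It went from 2 to 34 tags at chr2:119332001-119333000, a ratio of 22.1 (5.67 to 190), from 13 to 95 at chr11:33992001-33994000, a ratio of 9.50 (5.30 to 18.5), and from 24 to 146 at chr10:57874001-57877000, a ratio of 7.91 (5.11 to 12.7). In the other direction it went from 91 to 6 tags at chr13:96119001-96120000, a ratio of 0.0858 (0.0307 to 0.194). At chr9:21446001-21447000 it went from 35 tags to 1 and at chr8:110424001-110425000 from 33 to 1, with ratios of 0.0372 (0.000915 to 0.221) and 0.0394 (0.000969 to 0.235). The sites chr11:78912001-78913000 and chr5:110550001-110551000 each went from 26 tags to 1, a ratio of 0.05002 (0.00122 to 0.304). None of these 10 regions held an E2A peak. Few H3K4me1 regions did, with a spread E2A peak in 561 of the 45177 autosomal regions, so this is not particular to the 10.

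Spread E2A peaks lay mostly in H3K4me1 regions. Of the 742 spread peaks, 78.2% (exact binomial interval 75.02 to 81.1) lay in day 0 regions and 72.5% (69.1 to 75.7) in day 2 regions, and the median H3K4me1 density within 1 kb was 7.08 RPM at day 0 and 6.76 at day 2, with 1.55 in the input. At as many random positions the shares were 3.64% and 4.45%, and the median densities were 0.423, 0.472 and 0.774 RPM. Of the 354 narrow peaks, 11.6% (8.44 to 15.4) and 17.8% (14.0 to 22.2) lay in such regions. All 1096 peaks together gave 56.7% (53.7 to 59.6) at day 0 and 54.8% (51.8 to 57.8) at day 2.

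The mean H3K4me1 profile across the spread peaks had a trough over the peak centre at day 0. The mean density at the centre was 0.652 times that of the shoulders 250 to 550 bp away at day 0 and 0.985 times at day 2, while the input gave 1.24. At the narrow peaks the same H3K4me1 ratio was 2.86 at day 0 and 6.63 at day 2, so the day 2 H3K4me1 library held relatively more tags at the centres of both kinds of peak. The trough was deep at day 0 both at spread peaks with lower E2A at day 2 (0.662) and at those that met neither condition (0.611), and the day 2 values there were 1.14 and 0.876. At the 32 peaks with higher E2A the values were 1.51 at day 0 and 1.52 at day 2. Their median H3K4me1 density within 1 kb, 1.12 RPM at day 0 and 1.02 at day 2, was close to the 0.995 RPM of the input. A trough therefore could not be judged at these peaks. In the E2A libraries the centre stood 16.4-fold over the outer flanks, near 3 kb from the centre, at day 0 and 8.94-fold at day 2.

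**Figure D3:**
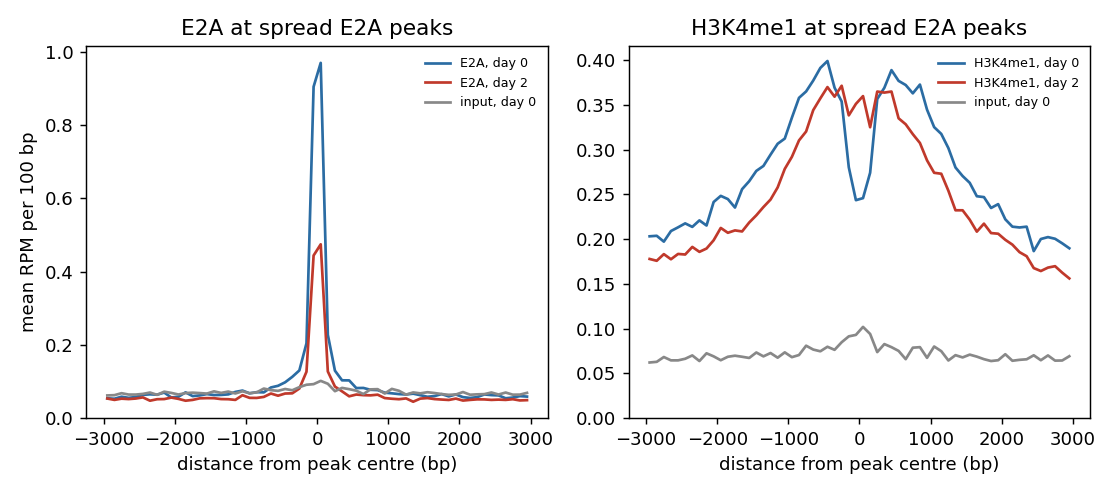
Mean RPM per 100 bp (vertical axes) by distance from the centres of the 742 spread E2A peaks (horizontal axes, bp), for E2A (left) and H3K4me1 (right) at day 0 (blue) and day 2 (red), with the day 0 input (grey). E2A at the centre is lower at day 2, and the H3K4me1 trough at the centre, 0.652 of the shoulders at day 0, is 0.985 at day 2.

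The next comparison asks whether H3K4me1 differed together with E2A at the same sites. Where E2A was lower at day 2, the median ratio of H3K4me1 tags within 1 kb was 0.817 (0.757 to 0.875) over 299 peaks, against 1.17 (1.14 to 1.21) over the 755 peaks that met neither condition and 1.17 (0.975 to 1.53) over the 42 higher peaks. For spread peaks alone these medians were 0.828 (0.762 to 0.881), 1.08 (1.05 to 1.11) and 0.996 (0.845 to 1.43). Of the 290 spread peaks with lower E2A, 197 had an H3K4me1 ratio below 1, and their share in H3K4me1 regions was 77.6% at day 0 and 64.5% at day 2. At 4 of the 5 sites with the lowest E2A ratio the H3K4me1 ratio was also below 1, from 0.448 at chr13:54993935-54994134 to 0.630 at chr8:11506898-11507097, while it was 1.32 at chr8:86954401-86954600.

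Across the 742 spread peaks the log ratios of E2A and H3K4me1 had a Spearman rho of 0.386 and a Pearson r of 0.356, and across the 320 with at least 20 E2A tags rho was 0.441. The narrow peaks gave a rho of 0.0551, a Pearson r of 0.291 and a median H3K4me1 ratio of 1.42 (1.34 to 1.52). The highest E2A sites on chr17 and chr6 had H3K4me1 ratios of 2.68 and 2.31 within 1 kb, the centre included. At the chr6 site the central 200 bp held 18 of 44 H3K4me1 tags at day 0 and 47 of 78 at day 2. The chr6 ratio therefore rests in part on the centre, and a ratio without it is not given for either site. With the 250 bp nearest the centre left out, the median H3K4me1 ratio out to 1 kb was 0.975 (0.867 to 1.04) at narrow peaks, 0.905 (0.867 to 0.946) at all spread peaks and 0.714 (0.67 to 0.796) at the 290 spread peaks with lower E2A, against 0.992 (0.963 to 1.02) at all spread peaks with the centre kept. These correlations are across peaks within 1 pair of libraries, and peaks are not independent replicates, so no p-value is given.

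The sex chromosomes differed between the days in both antibodies. Chromosome X held 2.5% of E2A tags at day 0 and 4.78% at day 2, and 1.73% and 2.59% of H3K4me1 tags, with 2.38% in the day 0 input. Chromosome Y held 670 RPM in E2A at day 0, 283 in H3K4me1 at day 0 and 583 in the input, against 8.09 and 9.67 in E2A and H3K4me1 at day 2. In 10 kb bins without an E2A peak or H3K4me1 region, the ratio of day 2 to day 0 relative to the autosomes was 1.95 (1.93 to 1.96) for X in E2A and 1.61 (1.60 to 1.62) in H3K4me1, and 0.0105 and 0.0333 for Y. Single autosomes ranged from 0.984 to 1.009 in E2A and from 0.987 to 1.010 in H3K4me1. On X, the median ratio of the H3K4me1 regions was 1.30 (1.252 to 1.355), and 23 of the 26 E2A peaks were narrow; the spread peaks of the autosomes alone had the same median E2A ratio, 0.413, as all spread peaks.

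**Figure D4:**
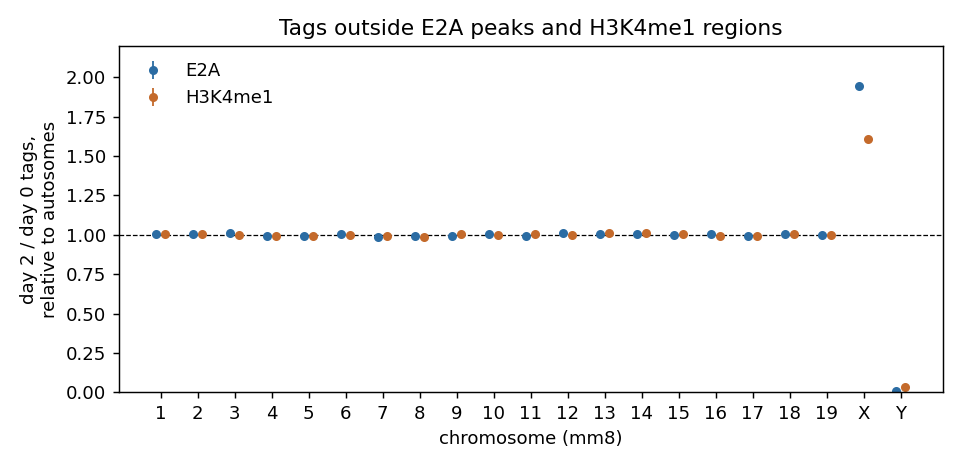
Ratio of day 2 to day 0 tags per chromosome relative to the autosomes (vertical axis) in 10 kb bins without E2A peaks or H3K4me1 regions, for E2A (blue) and H3K4me1 (orange); chromosomes are on the horizontal axis and the 95% counting intervals are mostly smaller than the points. The autosomes lie between 0.984 and 1.010, X at 1.95 and 1.61, and Y at 0.0105 and 0.0333.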

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

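The settings autosomes only and spread peaks only were chosen after the data were seen. Of 84 values under other settings, 58 stayed within 1.5 times the main count or within the main interval, 26 moved, and no ratio whose interval left out 1 changed direction. The H3K4me1 ratio at peaks with higher E2A, 1.17 with an interval that held 1, was 0.996 in spread peaks alone. H3K4me1 regions were more numerous at day 0 in the main setting, and at day 2 with all reads kept (38799 and 38870), at 5 fold over input and on the autosomes alone (38537 and 38541), so their order between the days is not settled. Keeping all reads gave 1160 E2A peaks at day 0, 767 at day 2 and 501 shared. The median E2A ratio was then 0.701, and 92 peaks were higher at day 2. With all reads, 49.9% of peaks lay in day 0 H3K4me1 regions. The same setting gave 71.9% of H3K4me1 base pairs shared and a median H3K4me1 ratio of 1.01. A fragment length of 150 bp gave 790 E2A peaks at day 0, 277 at day 2 and 193 shared. At 8 fold over input there were 605 E2A peaks at day 0 and 377 at day 2, and 52.9% of E2A peaks lay in H3K4me1 regions. At 5 fold over input there were 18675 and 19614 H3K4me1 regions at day 0 and day 2, with 65.3% of base pairs shared. Equal depth gave 65.9% shared. At full depth, counting a region only when no less of it lay inside than outside the other day's regions gave 67.5%. Scaling to tags outside regions gave a median H3K4me1 ratio of 1.02, and subtracting the input gave 4811 lower regions. Within 2 kb the H3K4me1 ratio was 0.752 at peaks with lower E2A and 1.09 at those that met neither condition.

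Calling and scaling anew on the autosomes alone gave 72.3% of H3K4me1 base pairs shared and a median H3K4me1 ratio of 1.02, while the autosomal part of the main regions had a median of 1.003 (0.998 to 1.007). Spread peaks alone gave 206 E2A peaks at day 2, 119 shared, a median E2A ratio of 0.413, 78.2% in H3K4me1 regions and an H3K4me1 ratio of 1.08 at peaks that met neither condition; these 206 and 119 count each day's own footprint, hence the small differences from the 207 and 120 of the pooled footprint. Fewer peaks under stricter settings follow from their construction, and for the other shifts the cause was not tested. Every setting run left the median E2A ratio below 1. Scaling to the peaks shared by both days gave 0.602, but 185 of those 305 peaks were narrow. Scaling to the 120 shared spread peaks, whose median ratio was 0.739, was not run. The scalings run therefore do not decide whether the immunoprecipitation was weaker at day 2. Gene lists and their 2 alternatives were not run, for want of an mm8 annotation. Leaving out a library was not possible with 1 per group. No paired analysis was possible because each group has 1 library. The depth of the E2A libraries limits single peaks: the median spread peak had 13 tags at day 0 and 6 at day 2.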

Other observations

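The test of animals of another sex was chosen after the X and Y totals were seen. The test of a pile-up without the E2A antibody kept its bounds but was reworded after its result. The test of E2A binding alone replaced, after its value was seen, one on the strand distance that the definition of narrow peaks had fixed in advance. The counts of neighbouring peaks, the split of H3K4me1 regions by E2A peaks and the division into spread and narrow peaks were likewise chosen after the data were seen, as was the test of H3K4me1 over all spread peaks without their centres.

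Spread E2A peaks lay in groups along the chromosomes. Of the 742 spread peaks, 220 (29.6%) had another spread peak within 50 kb, against a median of 27 and at most 53 in 100 draws of random positions. Of the 354 narrow peaks 7 had such a neighbour, against a median of 6 and at most 17. The draws were not matched for H3K4me1.

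H3K4me1 regions that held a spread E2A peak were slightly lower at day 2. The median ratio was 0.906 (0.875 to 0.947) in 561 autosomal regions with such a peak, 26 of them lower and 6 higher, and 1.004 (1.0004 to 1.009) in 44616 regions without one. Among regions of 5 kb or more the medians were 0.952 (0.906 to 0.988) in 358 regions with a peak and 1.018 (1.009 to 1.028) in 5877 without one. These regions were not matched for tag density.

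The first pattern is the shift of X and Y between the days. A gain of E2A or H3K4me1 at sites on X is argued against by bins without peaks or regions, where X was 1.61 times as frequent at day 2 in H3K4me1, above the bound of 1.5 set for this. Animals of another sex at day 2 may account for the E2A ratio of 1.95 on X and the Y ratios of 0.0105 and 0.0333. The H3K4me1 ratio of 1.61 fell short of the range of 1.7 to 2.3 that this predicted in both antibodies. That prediction was thus not met in full, and the explanation stays open. The Y ratios, far below those of any autosome in both antibodies, argue against an equal share of Y-bearing cells on both days. The labels used here do not give the sex of the mice. If sex did differ, it cannot be separated from the treatment in any comparison of the days.

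The second pattern is the narrow E2A peaks. E2A binding alone is argued against by H3K4me1 tags at the same autosomal sites, whose median interquartile range within 100 bp was 34.3 bp, against 85.3 bp at spread peaks. A pile-up of tags that does not need the E2A antibody may account for them, since H3K4me1 at day 0 also stood 3.50-fold over the surrounding 10 kb and the E2A ratio between the days was near 1. In H3K4me1 at day 2 the fold was 8.04, so the pile-up was not constant between the days in that antibody, and the cause was not tested. Copies absent from the mm8 assembly stay open: before any comparison with the input, the input stood 2.43-fold over its surroundings at narrow day 0 candidates, between the bounds of 2 and 3, and 1.96-fold at day 2 candidates, just under the lower bound, while spread day 0 candidates gave 2.40, so the excess was not particular to narrow peaks. The criteria for a peak set the E2A and input folds at these sites in part, so these do not weigh for or against E2A binding on top of a pile-up, which is not excluded.

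The third pattern is the lower E2A density at spread peaks at day 2. Lower depth is argued against by libraries thinned to 7293482 tags, where day 2 had 0.304 times the spread peaks of day 0, and counting error by random divisions, with at most 39 lower peaks against 339 on the autosomes. One common factor, such as a weaker immunoprecipitation, stays open: the dispersion of 2.63 around a factor of 0.477 in 320 peaks exceeded the 0.870 to 1.15 of simulated counts, but separate libraries can differ by more than counting error, so this decides nothing. A loss of H3K4me1 at the 290 peaks with lower E2A cannot be told apart from the E2A difference. The H3K4me1 ratio there was 0.828 within 1 kb, between the bounds of 0.8 and 0.9, and 0.714 without the centre. For a loss over all spread peaks, the ratio of 0.992 (0.963 to 1.02) lay above 0.9. That ratio includes the centre, where the day 2 H3K4me1 library held relatively more tags. Without the centre it was 0.905 (0.867 to 0.946) out to 1 kb and 0.881 (0.842 to 0.914) out to 2 kb. These lay on either side of 0.9 and both intervals held it, so a loss over all spread peaks stays open. Lower E2A occupancy after the CD3e signal, a possible sex difference and differences between single libraries also remain open, since 1 library per group tests none of them.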
